A study of Mus musculus with 15 samples.

How the data were processed

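The series was analysed from the gene counts deposited by the authors, with 48440 genes in 15 libraries. Per the labels, total RNA from C57BL/6 lung fibroblasts kept at 3% oxygen went into TruSeq RNA libraries. Per the submitters' processing notes, reads were counted with featureCounts on mm10 and SAMtools 1.3.1 was used. The aligner and the strandedness are not given in the sources used here, so antisense reads and overlapping genes could not be told apart. Gene IDs were matched to GENCODE vM21 symbols (GRCm38), which named 48058 genes and left 382 without a symbol. The design had 5 groups of 3, with replicates from 3 strains per genotype, and all 15 libraries were used.

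The authors also deposited TPM for 48082 genes, and the same values for a subset of 15515 genes whose filter is not stated. Per library the deposited TPM were the counts divided by gene length and scaled to a fixed sum. Of 201525 values with a count of at least 50 checked on this relation 100.0% lay within 2%, with a largest deviation of 1.29%. The 358 genes of the count table outside the TPM table entered the count-based tests alone. TPM carries the same reads as the counts, so the TPM fits are a second treatment of the same data and not a second measurement.

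The choices in this paragraph and the 2 that follow were made before the data were examined, except where stated. Genes passed the filterByExpr function of edgeR 4.0.16 by group, libraries were normalised by TMM, and a single quasi-likelihood fit with robust estimation and a mean per group held all 15 libraries (R 4.3.3). Each comparison was a contrast of that fit, with p adjusted by Benjamini and Hochberg over the genes tested and a threshold of 0.05. The comparisons were the genotypes at either passage, passage within either genotype, irradiation against passage 2 and against passage 8, the difference of the passage effects, and the difference between irradiation and Atm-/- passage. SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, CPM (counts per M counts) are TMM-normalised, and SD is over the 3 replicates. Named genes were the 10 with the largest fold changes each way (5 for irradiation against passage 8 and the 2 differences of effects) among those passing at a mean log2 CPM of at least 2, without overlap between groups where 2 groups were compared and without a predicted or clone-based symbol, up to 4 members per described list with the lowest p, and Atm.

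Of 24 gene lists written from general knowledge, 23 entered set tests. They were p53 target genes, CDK inhibitors and senescence markers, senescence-associated secretory genes, interferon-stimulated genes, cytosolic nucleic acid sensing, NF-kB feedback and target genes, mitosis and G2/M genes, and DNA replication and S phase genes. Further lists were double-strand break signalling and repair, extracellular matrix and myofibroblast genes, lysosome and autophagy genes, antioxidant and NRF2 target genes, cholesterol synthesis genes, Atm neighbours on chromosome 9, immediate early genes and mitochondrially encoded genes. Markers of resident lung fibroblasts, macrophages, endothelial, epithelial and mesothelial cells, smooth muscle and pericytes, and lymphocytes completed them. Sex-linked genes were read per library. Results for some single genes are not reported here. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation and fry, which tests against no change, beside it. Which lists are described per comparison was settled after the values were seen.

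Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, and a strict filter of at least 1 CPM in 3 libraries with a mean count of at least 50. Others were a fit of only the groups compared, limma on log2(TPM + 1) and log2(TPM + 0.1) with genes at 0.5 TPM or more in 3 libraries, and log2(TPM + 1) in the deposited subset. Each library was left out in turn, and the replicate number was entered as a block. A fit of 13 libraries, without the pair with the fewest genes detected, and 2 further pairs of fold changes were added after the data were seen.

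The labels do not state which libraries came from the same strain, and numbers were taken as strains within a genotype. After group means were removed, same-numbered libraries had correlations of 0, -0.18 and -0.20 between Atm+/+ passages, -0.05, 0.19 and 0.03 between Atm-/- passages and -0.01, 0.14 and 0.09 between irradiated and unirradiated cells. Same-numbered Atm+/+ passage 8 and irradiated libraries had 0.09, 0.06 and 0.04. Across genotypes, where only the number is shared, they were 0, 0.22 and -0.03 at passage 2 and -0.06, -0.09 and -0.16 at passage 8. The fit without a block was kept, and the block is given where it changed the call of a described list.

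Replicate correlations of log2 CPM ran from 0.962 to 0.999, no libraries were identical, and the common biological coefficient of variation was 0.314. The first 3 principal components took 41.1%, 30.1% and 10.1% of the variance. For a gene with 0 counts in a group the fold change is a bound with 3 counts set over the group, and for 1 to 3 counts a ratio with a 95% interval. These intervals cover counting error alone and not the spread between strains. Genes that share reads with near-identical copies, such as Ifit3, Apol9a, Tgtp1, Plac9a, Plac9b and the histone genes, carry an added uncertainty that was not measured.

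The fits were tested on simulated data with the mean levels, library sizes and gene-wise dispersions of these libraries and 100 genes changed at each of 2 folds. At 2-fold edgeR recovered 17% of changed genes for the genotypes at passage 2 (17830 genes), 22% at passage 8 (17814), 21% for Atm+/+ passage (17857) and 23% for Atm-/- passage (17814). It recovered 20% for irradiation and 22% for irradiation against passage 8 (17849 genes each), and 6% for the difference of passage effects (17814). At 4-fold these shares were 58%, 66%, 60%, 64%, 61%, 66% and 43%, in the same order. Calls among unchanged genes were 1 to 5 in edgeR and 27 to 61 in DESeq2. A list of 39 or 40 genes shifted 1.5-fold was called by camera in all 7 comparisons simulated, with either correlation. Of 23 random lists 0 were called. Genes were drawn independently of each other, so correlation within lists was absent. The simulation therefore does not show how often camera calls lists of correlated genes wrongly. The difference between irradiation and Atm-/- passage was not simulated.

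Pairs of comparisons were set side by side by Pearson's and Spearman's correlation over the genes tested and for pairs that share no library, by shared calls against n1 × n2 / N. For pairs sharing Atm+/+ passage 2, unchanged groups were simulated 20 times, controls included, with the same gene-wise dispersion in every group. Neighbourhood of Atm was tested within 20 Mb by Fisher's exact test. Samples were regrouped in 10 splits per comparison. Reads were not analysed here, so the deleted part of Atm, splicing and copies of repeats were not examined.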

Results

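RNA was sequenced from mouse primary lung fibroblasts in 5 groups of 3 libraries. Atm+/+ and Atm-/- cells were taken at passage 2 and at passage 8, and Atm+/+ cells labelled passage 2 were taken 10 days after 10 Gy of X-rays. Within a group each library came from a different fibroblast strain, so the spread between replicates includes differences between strains. Library totals were 33.0, 34.2 and 23.6 M (mega) counts in Atm+/+ passage 2 (replicates 1 to 3, in this order throughout), and 34.8, 36.1 and 34.4 in Atm-/- passage 2. They were 36.5, 30.3 and 37.1 in Atm+/+ passage 8, 34.0, 31.0 and 13.6 in Atm-/- passage 8, and 37.6, 39.2 and 34.1 in the irradiated cells. After the filter on low counts, 18167 genes were tested in each comparison. Levels below are normalised counts per M counts (CPM) as mean ± SD with n = 3, and fold changes are given on the log2 scale with their standard error (SE).

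A pair of libraries stood apart from their groups. At equal depth Atm+/+ passage 2 replicate 3 held reads for 17216 genes and Atm-/- passage 8 replicate 3 for 15037, against at least 20095 in each of the other 13 libraries. Of 9621 genes with a median of at least 10 CPM over all libraries, 161 and 269 lay under 0.1 of their median in these libraries. The next highest number was 113, in Atm-/- passage 8 replicate 1. Ribosomal and miscellaneous RNA genes took 0.732% and 1.85% of their counts, and 0.449% or less elsewhere. Xist, the RNA that coats the inactive X chromosome, was at 148.8 CPM in Atm-/- passage 2 replicate 3 and at 135.8 CPM in Atm-/- passage 8 replicate 3, and at 0.111 CPM or less in the other 13 libraries. The Y-linked genes Ddx3y and Kdm5d were at 0 CPM in those same libraries. The labels do not give the sex of the mice.

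**Figure D1:**
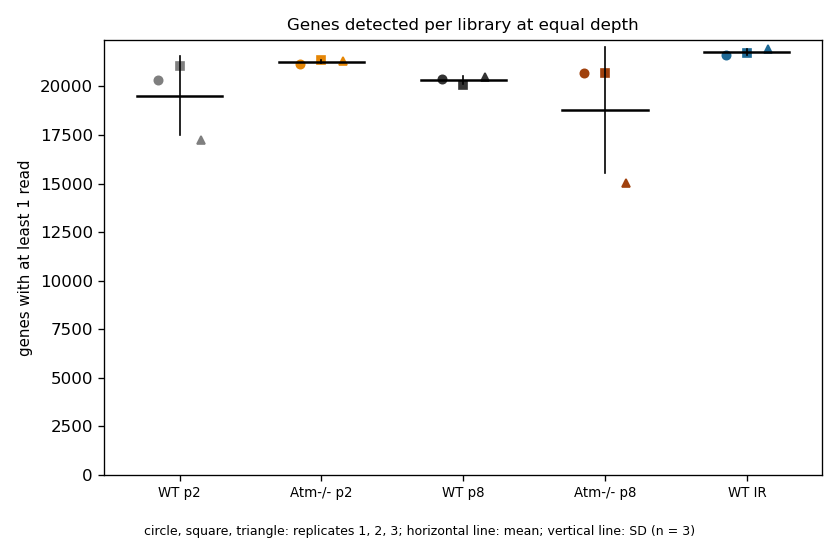
Number of genes with at least 1 read after every library was brought to equal depth, with 1 point per library (y axis, genes) and the 5 groups along the x axis. Atm+/+ passage 2 replicate 3 (17216 genes) and Atm-/- passage 8 replicate 3 (15037 genes) lie below the other 13 libraries, which start at 20095.

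Atm, the kinase that signals DNA double-strand breaks, had reads in every library. Its level in the replicates was 1.12, 0.877 and 3.10 CPM in Atm+/+ passage 2, 1.61, 0.966 and 1.91 CPM in Atm-/- passage 2, and 1.52, 1.42 and 2.00 CPM in Atm+/+ passage 8. It was 0.873, 1.09 and 2.37 CPM in Atm-/- passage 8 and 1.65, 2.01 and 1.40 CPM in the irradiated cells. Between genotypes the log2 fold change was -0.17 (SE 0.52, edgeR adjusted p = 0.883) at passage 2 and -0.24 (SE 0.53, edgeR adjusted p = 0.788) at passage 8. Sign and size rested on single libraries. In the 13 libraries, a fit chosen after seeing the data, Atm was at 0.60 at passage 2 (adjusted p = 0.310) and -0.73 at passage 8 (adjusted p = 0.119). Leaving out 1 library gave -0.47 (without Atm+/+ passage 2 replicate 2) to 0.61 (without Atm+/+ passage 2 replicate 3) at passage 2, and -0.74 (without Atm-/- passage 8 replicate 3) to 0.03 (without Atm-/- passage 8 replicate 1) at passage 8. The gene lies on chromosome 9, 53439149 to 53536740, minus strand (GRCm38/mm10). The labels do not give which part of it the knockout removes, so counts over the whole gene do not check the genotype labels. Of the 11 tested genes in the list of Atm neighbours, 0 passed in edgeR in either genotype comparison. Within 20 Mb of Atm 353 genes were tested, of which 6 (1.70%) passed at passage 2 and 41 (11.6%) at passage 8. Among genes elsewhere 0.950% and 9.27% passed (two-sided Fisher's exact test, p = 0.160 and p = 0.139).

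The comparison of Atm-/- with Atm+/+ cells at passage 2 asks what loss of Atm changes in early cultures. Interferon-stimulated genes, which cells switch on after interferon or on sensing foreign nucleic acid, were higher without Atm. Isg15, a ubiquitin-like antiviral protein, rose from 40.3 ± 4.91 to 294.5 ± 49.3 CPM (SD, n = 3), a log2 fold change of 2.87 (SE 0.24, edgeR adjusted p = 5.2e-05). Usp18, which removes Isg15 from proteins, rose from 4.98 ± 1.75 to 49.1 ± 8.69 CPM (SD, n = 3), by 3.31 (SE 0.27, edgeR adjusted p = 5.2e-05). Ifi44 rose by 3.15 (SE 0.24), Rtp4 by 2.70 (SE 0.23) and Zbp1, a sensor of Z-form nucleic acid, by 2.13 (SE 0.24, edgeR adjusted p = 0.000761). Myh11 and Lmod1, contractile genes of smooth muscle, rose by 1.96 (SE 0.23, edgeR adjusted p = 0.000887) and 1.34 (SE 0.20). The gelatinase gene Mmp9 fell by 2.62 (SE 0.32, edgeR adjusted p = 0.00107), from 204.7 ± 35.5 to 33.2 ± 8.70 CPM (SD, n = 3), and the matrix gene Dpt by 2.44 (SE 0.34).

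Of 56 interferon-stimulated genes tested, 38 rose, 0 fell and 18 did not pass in edgeR, and 46 rose when adjusted over the list alone. Their median log2 fold change was 1.52 (camera adjusted p = 2.62e-42, and 0.0919 with an estimated correlation). Among 17 genes of cytosolic nucleic acid sensing 4 rose and 13 did not pass, with 6 higher over the list alone (camera adjusted p = 0.0792, range over the alternatives 0.0146 to 0.648). It passed without Atm+/+ passage 2 replicate 3 (adjusted p = 0.0254) and without Atm-/- passage 2 replicate 1 (adjusted p = 0.0436). As defined, the sensing list shares Ifih1, Ddx58, Zbp1 and Ifi204 with the interferon-stimulated list, so these lists are not separate observations. Macrophage markers lay lower, with a median of -1.11 over 21 genes (camera adjusted p = 9.7e-14, and 0.0998 with an estimated correlation). In that list 1 gene fell and 20 did not pass, and 15 were lower over the list alone. Cholesterol synthesis genes had a median of -0.34 over 25 genes, of which 0 passed in edgeR and 1 was higher and 8 lower over the list alone (camera adjusted p = 0.000275, and 0.0998 with an estimated correlation). Of 35 p53 target genes 2 rose and 33 did not pass, with 8 higher and 2 lower over the list alone and a median of 0.33 (camera adjusted p = 0.00362, and 0.424 with an estimated correlation).

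Among 32 extracellular matrix and myofibroblast genes 5 rose and 27 did not pass, with 9 higher and 1 lower over the list alone and a median of 0.22. The set test gave adjusted p = 0.0147 in camera, 0.676 with an estimated correlation and 0.0789 without Atm-/- passage 2 replicate 3 (range over the alternatives 0.000389 to 0.676). Ccn2, a matricellular growth factor, rose by 1.41 (SE 0.17, edgeR adjusted p = 0.00082). Among 14 smooth muscle and pericyte markers 4 rose and 10 did not pass, with 5 higher over the list alone and a median of 0.40. For this list the camera adjusted p was 0.0206, with 0.648 for an estimated correlation, 0.0854 without Atm-/- passage 2 replicate 3 and 0.0515 with the replicate number as a block (range over the alternatives 0.00160 to 0.648). NF-kB target genes had a median of -0.34 with 1 of 25 lower, 24 not passing, and 1 higher and 4 lower over the list alone (camera adjusted p = 0.0206, and 0.648 with an estimated correlation, 0.219 without Atm+/+ passage 2 replicate 2 and 0.317 in fry). Endothelial markers had a median of -0.49 with 0 of 16 genes passing in edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.00794, and 0.676 with an estimated correlation and 0.395 in fry). Without Atm+/+ passage 2 replicate 2 their mean went from -0.44 to 0.01 (0.420), and without Atm-/- passage 2 replicate 1 the adjusted p was 0.112.

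In total 114 genes rose and 62 fell, 176 of 18167, of which 90 and 49 changed at least 2-fold. The replicates of the groups did not overlap for 4687 genes (25.8%, against 10% by chance). DESeq2 counted 863 genes, a fit of only the 2 groups compared counted 40, and the fit of the 13 other libraries, chosen after seeing the data, counted 989. Leaving out 1 library gave between 61 genes (without Atm-/- passage 2 replicate 1 or 2) and 1787 (without Atm+/+ passage 2 replicate 2), and Ccn2 did not pass in the fit of only these groups.

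At passage 8 the same comparison asks what loss of Atm changes after serial culture. Interferon-stimulated genes were again higher without Atm. Ifit3, an antiviral protein, rose from 60.8 ± 18.1 to 408.3 ± 69.9 CPM (SD, n = 3), by 2.75 (SE 0.28, edgeR adjusted p = 0.000234). Oas2 and Oas1a, which make the activator of RNase L, rose by 4.19 (SE 0.44) and 2.91 (SE 0.26), Usp18 by 2.56 (SE 0.26) and Xaf1 by 1.72 (SE 0.15). Genes of the collagen matrix were lower. Col1a2 fell by 1.93 (SE 0.17, edgeR adjusted p = 0.000112), from 9919 ± 1118 to 2600.0 ± 442 CPM (SD, n = 3), Col1a1 by 2.09 (SE 0.22) and the collagen-binding integrin gene Itga11 by 2.92 (SE 0.31). The cell cycle inhibitor gene Cdkn2b rose by 1.26 (SE 0.20, edgeR adjusted p = 0.00279). Cdkn2a, which encodes p16 and p19ARF, rose from 47.6 ± 8.83 to 190.0 ± 50.6 CPM (SD, n = 3), by 2.00 (SE 0.41, edgeR adjusted p = 0.0102).

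Of 56 interferon-stimulated genes 33 rose, 0 fell and 23 did not pass in edgeR, and 46 rose over the list alone. Their median was 1.20 (camera adjusted p = 2.7e-29, and 0.127 with an estimated correlation). Cytosolic nucleic acid sensing genes had 2 of 17 higher, 15 not passing, and 7 higher and 1 lower over the list alone, with a median of 0.58 (camera adjusted p = 0.00208, and 0.177 with an estimated correlation). Of 32 extracellular matrix and myofibroblast genes 25 fell, 0 rose and 7 did not pass, with 27 lower and 1 higher over the list alone. Their median was -0.95 (camera adjusted p = 2.89e-19, and 0.127 with an estimated correlation). Among 14 smooth muscle and pericyte markers 10 fell, 3 did not pass and Cspg4 rose by 2.83 (SE 0.43), and the counts were the same over the list alone. Their median was -1.40 (camera adjusted p = 3.66e-05, and 0.177 with an estimated correlation), and Myh11 fell by 2.06 (SE 0.23).

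Senescence-associated secretory genes had 18 of 56 lower, 3 higher and 35 not passing, with 21 lower and 6 higher over the list alone. Their median was -0.66, or -0.52 with 3 genes at 0 in one group set at their bound (camera adjusted p = 0.001, and 0.315 with an estimated correlation). Igfbp4 fell by 2.47 (SE 0.36), Igfbp5 by 1.75 (SE 0.24), the chemokine gene Cxcl12 by 1.81 (SE 0.28) and the protease gene Plau by 1.61 (SE 0.29). Resident lung fibroblast markers had 9 of 23 lower, 2 higher and 12 not passing, with the same counts over the list alone and a median of -0.64 (camera adjusted p = 0.000552, and 0.315 with an estimated correlation). NF-kB target genes had 5 of 25 lower, 20 not passing, and 8 lower over the list alone (camera adjusted p = 0.00378, and 0.324 with an estimated correlation), and a mean of -0.59 to -0.21 without 1 library. Lysosome and autophagy genes had 10 of 39 higher, 1 lower and 28 not passing, with 15 higher and 2 lower over the list alone. Their median was 0.26 (camera adjusted p = 0.000261, and 0.213 with an estimated correlation), with Gpnmb higher by 1.87 (SE 0.28). Their mean went from 0.27 to 0.06 without Atm-/- passage 8 replicate 1 (camera adjusted p = 0.00294).

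DNA replication and S phase genes had 7 of 40 higher and 33 not passing, with 7 higher over the list alone and a median of 0.25. The list had a camera adjusted p of 0.001, with 0.426 for an estimated correlation, and 0.122 without Atm-/- passage 8 replicate 1, where the mean went from 0.27 to 0.08 (range over the alternatives 9.13e-05 to 0.426). CDK inhibitors and senescence markers had 3 of 17 higher, 2 lower and 12 not passing, with 4 higher and 6 lower over the list alone (camera adjusted p = 0.723). Macrophage markers had 6 of 21 lower and 15 not passing, with 9 lower and 2 higher over the list alone (camera adjusted p = 0.0737), and passed with no filter (0.000619) and without Atm+/+ passage 8 replicate 1 (0.0287) or 3 (0.0465). Endothelial markers had 4 of 16 higher and 12 not passing, with 6 higher over the list alone and a median of 1.74 from low levels. Their camera adjusted p of 0.0491 (range over the alternatives 0.0149 to 0.612) did not pass with an estimated correlation (0.612), with no filter (0.0765), with the strict filter (0.192) or in fry (0.396). Nor did it without Atm+/+ passage 8 replicate 2 (0.0575), Atm-/- passage 8 replicate 2 (0.0919) or replicate 3 (0.186), or in the 13 libraries (0.267). Of 35 p53 target genes 5 rose, 4 fell and 26 did not pass, with 10 higher and 5 lower over the list alone. Their camera adjusted p was 0.0517 (range over the alternatives 0.0140 to 0.426), and it passed without Atm+/+ passage 8 replicate 1 (0.0459) or replicate 3 (0.0435) and without Atm-/- passage 8 replicate 3 (0.0151). It also passed with the replicate number as a block (0.0487), with DESeq2 size factors (0.0470) and in the 13 libraries (0.0140), and its mean went from 0.15 to 0.01 without Atm-/- passage 8 replicate 1.

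In total 913 genes rose and 780 fell, 1693 of 18167, of which 476 and 450 changed at least 2-fold, and 7238 genes (39.8%, against 10% by chance) did not overlap between the groups. On log2(TPM + 1) in limma, where the median of all genes lay at -0.30, the split was 367 higher and 1003 lower. DESeq2 counted 3525 genes, the 13 libraries gave 4629, and leaving out 1 library gave between 588 (without Atm+/+ passage 8 replicate 3) and 3390 (without Atm+/+ passage 2 replicate 3). A fit of only the 2 groups compared counted 18, and of the genes named for passage 8 it did not call Col1a1, Itga11, Cdkn2a, Cdkn2b, Cspg4, Myh11, Igfbp4, Igfbp5, Cxcl12 or Gpnmb, while Cdkn2a was also lost without Atm+/+ passage 8 replicate 2 (adjusted p = 0.0554).

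**Figure D2:**
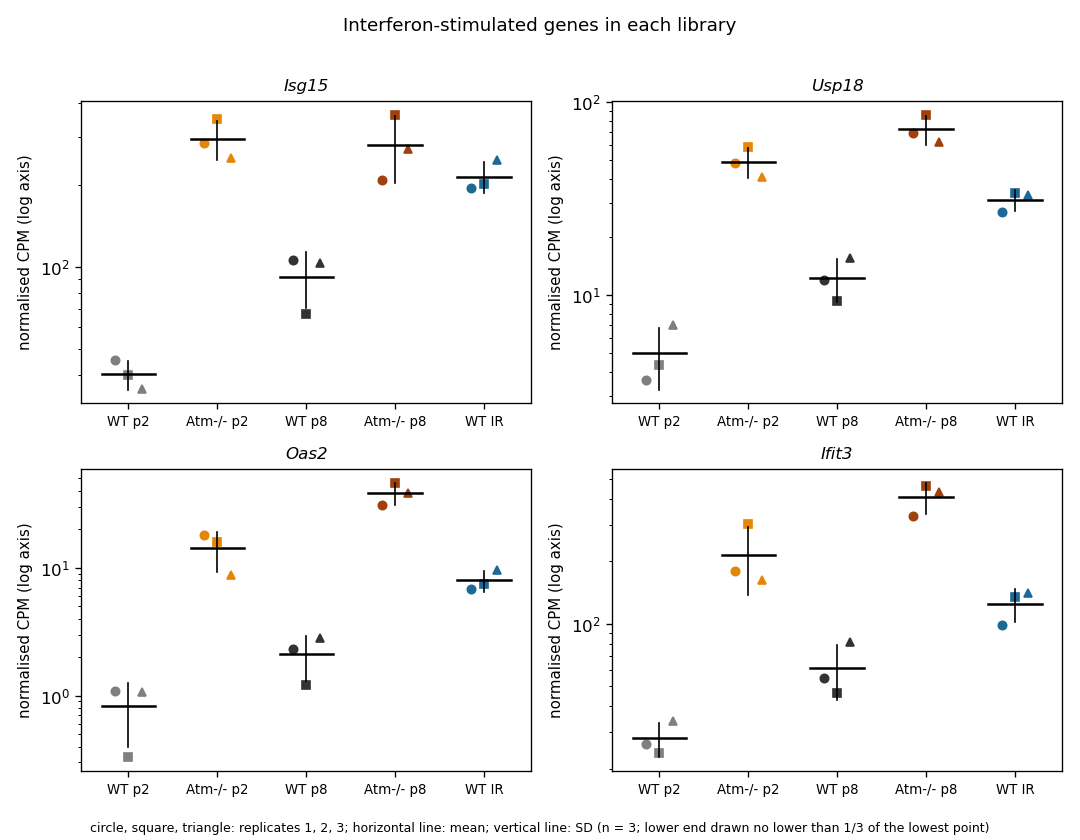
Normalised CPM (y axis, log scale) of Isg15, Usp18, Oas2 and Ifit3 in the 5 groups (x axis), with points for the 3 replicates, a horizontal line for the mean and a vertical line for the SD. Isg15 was at 40.3 CPM in Atm+/+ passage 2, 294.5 in Atm-/- passage 2 and 214.1 in the irradiated cells.

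Across the passages, 88 genes passed in both genotype comparisons. Of these 77 changed in the same direction, among them 30 of the 56 interferon-stimulated genes, and 11 changed in opposite directions. Among the 11 were 10 that were higher without Atm at passage 2 and lower at passage 8, contractile and matrix genes such as Myh11, Lmod1, Actg2, Cnn1, Acta2 and Thbs1, and also Akap12, Nexn and Ankrd1. The lens crystallin gene Crybb3 went the other way. At passage 2 Thbs1, Cnn1 and Actg2 did not pass in 5, 4 and 2 of the fits without 1 library, and Akap12, Nexn, Ankrd1 and Crybb3 were not followed in those fits. In the 13 libraries 442 genes passed at both passages, 322 in the same and 120 in opposite directions, and the 11 genes were among the latter. Fold changes of the genotype at passage 2 and at passage 8 had a correlation across genes of r = -0.081, which was 0.144 in the 13 libraries, 0.096 without Atm+/+ passage 2 replicate 3 and 0.048 without Atm-/- passage 8 replicate 3. Genes are not independent replicates.

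The difference between the passage effects of the genotypes asks whether loss of Atm alters what serial culture changes. Most matrix genes tested and some smooth muscle genes had a lower passage effect without Atm. Myh11 went from 91.0 ± 21.7 to 618 ± 81.2 CPM in Atm+/+ cells and from 353 ± 28.6 to 148 ± 45.5 CPM in Atm-/- cells (SD, n = 3), a difference of -4.02 on the log2 scale (SE 0.33, edgeR adjusted p = 0.000184). Thbs1, an activator of TGF-beta, differed by -3.07 (SE 0.41), Col1a1 by -2.28 (SE 0.30), Col1a2 by -1.78 (SE 0.24, edgeR adjusted p = 0.00333) and Ccn2 by -1.87 (SE 0.23). Among secretory genes Vegfa differed by -2.30 (SE 0.37, edgeR adjusted p = 0.0104) and Il11 by -2.18 (SE 0.36). Among smooth muscle genes Lmod1 differed by -2.67 (SE 0.28), Actg2 by -2.52 (SE 0.36) and Cnn1 by -2.31 (SE 0.37).

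Of 32 extracellular matrix and myofibroblast genes 21 had a lower passage effect without Atm, 0 a higher one and 11 did not pass, with 25 lower and 1 higher over the list alone. Their median difference was -1.17 (camera adjusted p = 1.1e-16, and 0.253 with an estimated correlation). Smooth muscle and pericyte markers had 6 of 14 lower, 1 higher and 7 not passing, with 10 lower and 1 higher over the list alone and a median of -2.06 (camera adjusted p = 3.57e-05, and 0.284 with an estimated correlation). Secretory genes of senescence had 12 of 56 lower, 2 higher and 42 not passing, with 17 lower and 3 higher over the list alone (median -1.01, camera adjusted p = 0.00151, and 0.647 with an estimated correlation). Lysosome and autophagy genes had 3 of 39 higher and 36 not passing, with 6 higher over the list alone (camera adjusted p = 0.0350, and 0.659 with an estimated correlation). They did not pass with no filter (0.125), with the strict filter (0.0757), with a strain block (0.0522), in fry (0.290) or in 5 of the fits without 1 library (0.0531 to 0.129), and their mean went from 0.16 to -0.07 without Atm-/- passage 8 replicate 1.

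Endothelial markers had 3 of 16 higher and 13 not passing, with 7 higher over the list alone and a median of 2.16. Camera gave them an adjusted p of 0.00993, with 0.684 for an estimated correlation, and 0.0758 without Atm+/+ passage 2 replicate 2 (range over the alternatives 5.98e-05 to 0.684). DNA replication genes had 2 of 40 higher and 38 not passing, with 2 higher over the list alone and a median of 0.18. For this list the camera adjusted p was 0.0239 (range over the alternatives 0.000140 to 0.684), and 0.684 with an estimated correlation. The replication list did not pass without Atm+/+ passage 2 replicate 2 (mean -0.11 against 0.19, adjusted p = 0.204), Atm-/- passage 8 replicate 1 (0.312) or Atm+/+ passage 8 replicate 1 (0.0568). Epithelial markers had 0 of 10 passing in edgeR and 2 higher over the list alone (median 1.46, camera adjusted p = 0.0447, and 0.659 with an estimated correlation). They did not pass with either other filter (0.0611 and 0.403), in the 13 libraries (0.676), in fry (0.290) or in 9 of the fits without 1 library (0.0531 to 0.240). Interferon-stimulated genes had 1 of 56 lower and 55 not passing, with 0 over the list alone and a median of -0.48. Their camera adjusted p of 0.146 ranged over the alternatives from 0.00337 to 0.773, and passed with a strain block (0.0337), without Atm-/- passage 2 replicate 3 (0.0210), Atm+/+ passage 8 replicate 2 (0.0273) and Atm-/- passage 8 replicate 2 (0.0101).

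In total 446 genes had a higher and 358 a lower passage effect without Atm, 804 of 18167. In limma on log2(TPM + 1), where the median of all genes lay at -0.52, the split was 177 and 656. With the strain as a block 144 genes passed, in a fit of only the 4 groups 120, in the 13 libraries 2556 and in DESeq2 3472. Leaving out 1 library gave between 79 genes (without Atm+/+ passage 8 replicate 3) and 4600 (without Atm+/+ passage 2 replicate 2).

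**Figure D3:**
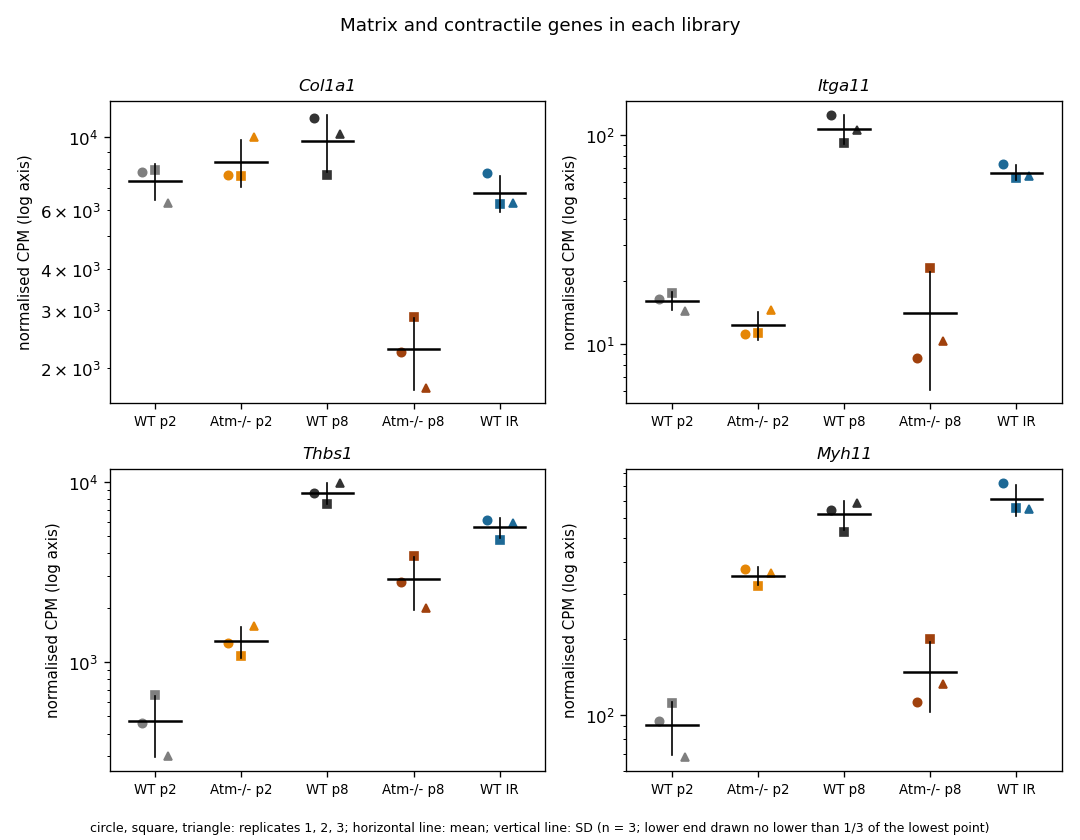
Normalised CPM (y axis, log scale) of Col1a1, Itga11, Thbs1 and Myh11 in the 5 groups (x axis), with points for the 3 replicates, a horizontal line for the mean and a vertical line for the SD. Myh11 was at 91.0 and 618 CPM in Atm+/+ cells at passages 2 and 8, and at 353 and 148 CPM in Atm-/- cells.

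The comparison of passage 8 with passage 2 in Atm+/+ cells asks what serial culture changes. Markers of macrophages and endothelial cells were lower at passage 8. Lyz2, a lysozyme of macrophages, fell by 5.54 (SE 0.38, edgeR adjusted p = 9.32e-07), from 1756 ± 255 to 37.7 ± 14 CPM (SD, n = 3), and the endothelial adhesion gene Pecam1 fell by 7.41 (SE 0.60, edgeR adjusted p = 2.93e-06), from 147.9 ± 58.6 to 0.875 ± 0.294 CPM. The lymphoid and endothelial GTPase gene Gimap4, with 0 counts at passage 8, was at least 804-fold lower, with the floor at 3 counts over the group. Matrix genes were higher, with Thbs1 rising from 471 ± 176 to 8691 ± 1170 CPM (SD, n = 3), by 4.20 (SE 0.32, edgeR adjusted p = 2.19e-06). Ccn2 rose by 3.06 (SE 0.17), the collagen crosslinking gene Lox by 1.80 (SE 0.15) and Itga11 by 2.73 (SE 0.30). The cell cycle inhibitor gene Cdkn1a rose by 0.62 (SE 0.13, edgeR adjusted p = 0.00441), and Mki67, a marker of cycling cells, fell by 1.14 (SE 0.18, edgeR adjusted p = 0.000462).

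Of 21 macrophage markers 20 fell and 1 did not pass, with the same counts over the list alone and a median of -5.84 (camera adjusted p = 3.57e-17, and 0.142 with an estimated correlation). Of 16 endothelial markers 14 fell and 2 did not pass, with the same counts over the list alone and a median of -6.37 (camera adjusted p = 8.13e-11, and 0.502 with an estimated correlation). Epithelial markers had 6 of 10 lower, 1 higher and 3 not passing, with 8 lower and 1 higher over the list alone (median -4.60, or -4.14 with the gene at 0 set at its bound; camera adjusted p = 0.0201, and 0.514 with an estimated correlation). The test of this list turned under the strict filter (0.984), and did not pass with only the groups compared (0.560), in the 13 libraries (0.343) or without Atm+/+ passage 2 replicate 2 (0.124) or 3 (0.110). Resident lung fibroblast markers had 8 of 23 lower, 2 higher and 13 not passing, with 10 lower and 2 higher over the list alone (camera adjusted p = 0.0137, and 0.514 with an estimated correlation, 0.0829 without Atm+/+ passage 2 replicate 2 and 0.135 with the strict filter). Extracellular matrix and myofibroblast genes had 18 of 32 higher, 2 lower and 12 not passing, with the same counts over the list alone and a median of 0.62 (camera adjusted p = 1.7e-07, and 0.514 with an estimated correlation). Immediate early genes had 6 of 16 higher and 10 not passing, with 7 higher over the list alone (camera adjusted p = 0.000627, and 0.514 with an estimated correlation), and the AP-1 gene Fosl1 rose by 2.73 (SE 0.14).

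DNA replication and S phase genes had 15 of 40 lower and 25 not passing, with 16 lower over the list alone and a median of -0.53 (camera adjusted p = 0.000141, and 0.514 with an estimated correlation). The helicase gene Mcm6 fell by 1.40 (SE 0.20) and the ligase gene Lig1 by 1.23 (SE 0.17). Mitosis genes had 7 of 35 lower and 28 not passing, with 7 lower over the list alone and a median of -0.42. Their camera adjusted p was 0.0238 (range over the alternatives 0.000125 to 0.682), with 0.682 for an estimated correlation, 0.426 without Atm+/+ passage 2 replicate 2 and 0.134 without Atm+/+ passage 8 replicate 1. Without Atm+/+ passage 2 replicate 2 the mean of the mitosis genes went from -0.27 to 0.09 and that of the replication genes from -0.51 to -0.19 (camera adjusted p = 0.0184). Of 35 p53 target genes 13 rose, 4 fell and 18 did not pass, with 16 higher and 5 lower over the list alone. The set test gave a camera adjusted p of 0.0238 (range over the alternatives 0.00375 to 0.514), with 0.514 for an estimated correlation and 0.0663 without Atm+/+ passage 2 replicate 2. Interferon-stimulated genes had 19 of 56 higher, 4 lower and 33 not passing, with 21 higher and 4 lower over the list alone and a median of 0.49. Camera gave them an adjusted p of 0.0137 (range over the alternatives 0.00106 to 0.682), with 0.682 for an estimated correlation and 0.124 without Atm+/+ passage 2 replicate 2. CDK inhibitors and senescence markers had 5 of 17 higher, 4 lower and 8 not passing, with the same counts over the list alone (median -0.02, mean 0.22, test up, camera adjusted p = 0.377, and 0.0161 in fry). Senescence-associated secretory genes had 16 of 56 higher, 16 lower and 24 not passing, with 19 and 18 over the list alone and a camera adjusted p of 0.823. The median (-0.16) and mean (-0.38, or -0.06 without Atm+/+ passage 2 replicate 2) of this list were negative while the direction of its test was up.

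In total 1780 genes rose and 2447 fell, 4227 of 18167, of which 990 and 1585 changed at least 2-fold, and 8626 genes (47.5%, against 10% by chance) did not overlap between the groups. On log2(TPM + 1) in limma, where the median of all genes lay at 0.19, the split was 1777 higher and 1580 lower. A fit of only the 2 groups counted 2665 genes and the 13 libraries gave 7418, while leaving out 1 library gave between 2186 (without Atm+/+ passage 8 replicate 3) and 7500 (without Atm-/- passage 8 replicate 3).

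The comparison of passage 8 with passage 2 in Atm-/- cells asks the same question without Atm. Macrophage and endothelial markers were again lower at passage 8, with Lyz2 falling by 5.40 (SE 0.37, edgeR adjusted p = 2.58e-06) and Pecam1 by 5.07 (SE 0.54, edgeR adjusted p = 4.05e-05). Spi1, the transcription factor PU.1 of macrophages, had 0 counts at passage 8 and was at least 175-fold lower. The complement gene C1qc, with 2 counts at passage 8, was lower by a ratio of 1930 (95% counting interval 533 to 15900). Cdkn2a rose from 13.9 ± 4.91 to 190.0 ± 50.6 CPM (SD, n = 3), by 3.78 (SE 0.45, edgeR adjusted p = 8.9e-05), and Cdkn2b by 1.90 (SE 0.20). Col1a1 fell from 8412 ± 1371 to 2285 ± 559 CPM (SD, n = 3), by 1.88 (SE 0.22, edgeR adjusted p = 7.66e-05), and the matricellular genes Postn and Tgfbi fell by 3.19 (SE 0.37) and 3.21 (SE 0.40). Pdgfra, a receptor of resident fibroblasts, fell by 1.75 (SE 0.22, edgeR adjusted p = 0.000144). The mesothelial gene Msln rose by 5.98 (SE 0.82, edgeR adjusted p = 0.000279), from 0.347 ± 0.188 to 22.1 ± 17.3 CPM (SD, n = 3).

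Of 21 macrophage markers 20 fell and 1 did not pass, with the same counts over the list alone. Their median was -6.49, or -5.52 with 2 genes at 0 set at their bound (camera adjusted p = 1.85e-16, and 0.163 with an estimated correlation). Of 16 endothelial markers 14 fell and 2 did not pass, with 15 lower over the list alone and a median of -4.33 (camera adjusted p = 4.33e-10, and 0.165 with an estimated correlation). Lymphocyte markers had 3 of 4 lower and 1 not passing, with 4 lower over the list alone (camera adjusted p = 0.00948, and 0.165 with an estimated correlation and 0.471 with no filter). Resident lung fibroblast markers had 12 of 23 lower, 1 higher and 10 not passing, with 15 lower and 1 higher over the list alone and a median of -1.01 (camera adjusted p = 1.45e-06, and 0.165 with an estimated correlation). Extracellular matrix and myofibroblast genes had 15 of 32 lower, 4 higher and 13 not passing, with 19 lower and 4 higher over the list alone and a median of -0.66 (camera adjusted p = 0.000164, and 0.363 with an estimated correlation). Smooth muscle and pericyte markers had 7 of 14 lower and 7 not passing, with 9 lower over the list alone and a median of -1.04 (camera adjusted p = 1.94e-05, and 0.165 with an estimated correlation).

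Secretory genes of senescence had 19 of 56 lower, 5 higher and 32 not passing, with 25 lower and 7 higher over the list alone and a median of -0.58 (camera adjusted p = 0.00653, and 0.363 with an estimated correlation). Within the list Igfbp5 fell by 4.16 (SE 0.27) and Csf1, the macrophage growth factor, rose by 2.65 (SE 0.22). Mitosis genes had 7 of 35 lower and 28 not passing, with 9 lower over the list alone and a median of -0.85 (camera adjusted p = 3.8e-07, and 0.363 with an estimated correlation), with Mki67 falling by 0.97 (SE 0.18). The fall was largest in Atm-/- passage 8 replicate 3, with a mean log2 level of 1.95 against 3.61 and 3.11 in its group mates, and the mean change went from -0.91 to -0.62 without it (camera adjusted p = 1.42e-07). Lysosome and autophagy genes had 10 of 39 higher, 3 lower and 26 not passing, with 13 higher and 4 lower over the list alone. Their test was up (camera adjusted p = 0.000936, and 0.309 with an estimated correlation) with a median of 0.25 and a mean of -0.02, or -0.21 to 0.07 without 1 library. Among the members that fell, Ctss, a cathepsin that is also in the macrophage list, fell by 6.98 (SE 0.50). CDK inhibitors and senescence markers had 4 of 17 higher, 1 lower and 12 not passing, with 4 and 4 over the list alone (median -0.34, mean -0.01, test up, camera adjusted p = 0.679). Mesothelial markers had 5 of 8 higher, 2 lower and 1 not passing, with the same counts over the list alone and a median of 4.38, or 3.58 with the gene at 0 set at its bound. Their camera adjusted p was 0.0242 (range over the camera alternatives 0.00798 to 0.927, and 0.00126 in fry), with 0.165 for an estimated correlation, 0.0507 without Atm-/- passage 2 replicate 1, 0.0915 without Atm-/- passage 8 replicate 3, and the opposite direction under the strict filter (0.927). In Atm+/+ passage 4 of the 8 mesothelial markers rose and 1 fell (median 1.97, or 1.44 with the bound, camera adjusted p = 0.555, range over the alternatives 0.285 to 0.987), with the same counts over the list alone. Between genotypes at passage 8, 4 were higher and 1 lower without Atm (median 1.19, camera adjusted p = 0.144, range over the alternatives 0.0566 to 0.854), again with the same counts. For the difference of passage effects 0 of 8 passed in edgeR and 1 was higher over the list alone (camera adjusted p = 0.329, range over the alternatives 0.167 to 0.892). Interferon-stimulated genes had 4 of 56 higher, 1 lower and 51 not passing, with the same counts over the list alone and a median of 0.03. Their camera adjusted p of 0.172 (range over the alternatives 0.00255 to 0.871) passed without Atm-/- passage 2 replicate 2 (0.00255) and without Atm-/- passage 8 replicate 1 (0.00898), and its direction turned without Atm-/- passage 8 replicate 2 (mean -0.22, adjusted p = 0.871).

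In total 864 genes rose and 1498 fell, 2362 of 18167, of which 417 and 1216 changed at least 2-fold, and 6723 genes (37.0%, against 10% by chance) did not overlap between the groups. In limma on log2(TPM + 1), where the median of all genes lay at -0.33, the split was 324 higher and 1953 lower. DESeq2 counted 3589 genes, a fit of only the 2 groups 868 and the 13 libraries 5026, while leaving out 1 library gave between 1476 (without Atm-/- passage 2 replicate 3) and 3544 (without Atm+/+ passage 2 replicate 3).

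Irradiated Atm+/+ cells were compared with unirradiated ones at passage 2. None of the latter is labelled as kept for 10 days, so dose and time in culture are not separated. Genes of cell division were lower and p53 target genes higher after irradiation. Mki67 fell from 54.0 ± 5.04 to 5.83 ± 1.15 CPM (SD, n = 3), by 3.21 (SE 0.19, edgeR adjusted p = 8.22e-07), and the topoisomerase gene Top2a by 2.57 (SE 0.18). Cdkn1a rose from 252.6 ± 14.6 to 943.9 ± 57.3 CPM (SD, n = 3), by 1.90 (SE 0.14, edgeR adjusted p = 2.93e-06), and the p53 targets Ccng1 and Pmaip1 rose by 2.03 (SE 0.22) and 2.58 (SE 0.34). Ccn2 rose by 2.96 (SE 0.17, edgeR adjusted p = 8.22e-07), Thbs1 by 3.57 (SE 0.31) and the smooth muscle actin gene Acta2 by 1.70 (SE 0.16). Isg15 rose to 214.1 ± 27.7 CPM (SD, n = 3), by 2.41 (SE 0.23, edgeR adjusted p = 2.65e-05), and Usp18 by 2.66 (SE 0.26). The chaperone gene Clu fell by 4.37 (SE 0.39, edgeR adjusted p = 1.37e-05) and Igfbp4 by 2.97 (SE 0.37).

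Mitosis genes had 25 of 35 lower and 10 not passing, with 29 lower over the list alone and a median of -2.14 (camera adjusted p = 8.01e-13, and 0.325 with an estimated correlation). DNA replication and S phase genes had 24 of 40 lower and 16 not passing, with 26 lower over the list alone and a median of -1.16 (camera adjusted p = 1.23e-09, and 0.311 with an estimated correlation). Double-strand break signalling and repair genes had 7 of 37 lower, 1 higher and 29 not passing, with the same counts over the list alone (camera adjusted p = 0.149, and 0.0294 in the 13 libraries). Of 35 p53 target genes 21 rose, 4 fell and 10 did not pass, with 24 higher and 4 lower over the list alone and a median of 0.73 (camera adjusted p = 8.54e-07, and 0.139 with an estimated correlation). Interferon-stimulated genes had 38 of 56 higher, 3 lower and 15 not passing, with 39 higher and 3 lower over the list alone and a median of 1.04 (camera adjusted p = 2.29e-10, and 0.325 with an estimated correlation). Extracellular matrix and myofibroblast genes had 17 of 32 higher, 4 lower and 11 not passing, with the same counts over the list alone and a median of 0.82 (camera adjusted p = 4.86e-06, and 0.325 with an estimated correlation). Cholesterol synthesis genes had 13 of 25 lower, 1 higher and 11 not passing, with the same counts over the list alone and a median of -0.55 (camera adjusted p = 4.73e-06, and 0.103 with an estimated correlation), with the sterol regulator Insig1 falling by 1.40 (SE 0.16).

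Senescence-associated secretory genes had 18 of 56 higher, 8 lower and 30 not passing, with 19 higher and 10 lower over the list alone and a median of 0.37. Csf1 rose by 3.19 (SE 0.22) and the stromelysin gene Mmp10 by 2.98 (SE 0.38). The set test of the secretory genes gave a camera adjusted p of 0.0465 (range over the camera alternatives 0.0124 to 0.558, and 0.00886 in fry), with 0.558 for an estimated correlation and 0.0570 with the strain as a block. It gave 0.0697 and 0.0893 without irradiated replicates 1 and 3, and 0.0666, 0.0684 and 0.0629 without Atm+/+ passage 2 replicates 1, 2 and 3, with a mean of 0.90 against 0.55 without replicate 2. CDK inhibitors and senescence markers had 3 of 17 higher, 5 lower and 9 not passing, with 3 higher and 6 lower over the list alone (camera adjusted p = 0.886). Endothelial markers had 10 of 16 lower and 6 not passing, with the same counts over the list alone and a median of -1.79 (camera adjusted p = 6.76e-07, and 0.325 with an estimated correlation). Macrophage markers had 4 of 21 lower and 17 not passing, with the same counts over the list alone and a median of -0.62. The list had a camera adjusted p of 0.0354 (range over the alternatives 0.00249 to 0.558), with 0.558 for an estimated correlation, 0.180 without irradiated replicate 2, 0.107 without Atm+/+ passage 2 replicate 3 (mean -0.27 against -0.53) and 0.220 in the 13 libraries.

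In total 2003 genes rose and 2995 fell, 4998 of 18167, of which 1145 and 1777 changed at least 2-fold, and 9991 genes (55.0%, against 10% by chance) did not overlap between the groups. On log2(TPM + 1) in limma, where the median of all genes lay at 0.33, the split was 4062 higher and 1592 lower. The 13 libraries gave 8561 genes, and leaving out 1 library gave between 2677 (without irradiated replicate 1) and 8275 (without Atm-/- passage 8 replicate 3).

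**Figure D4:**
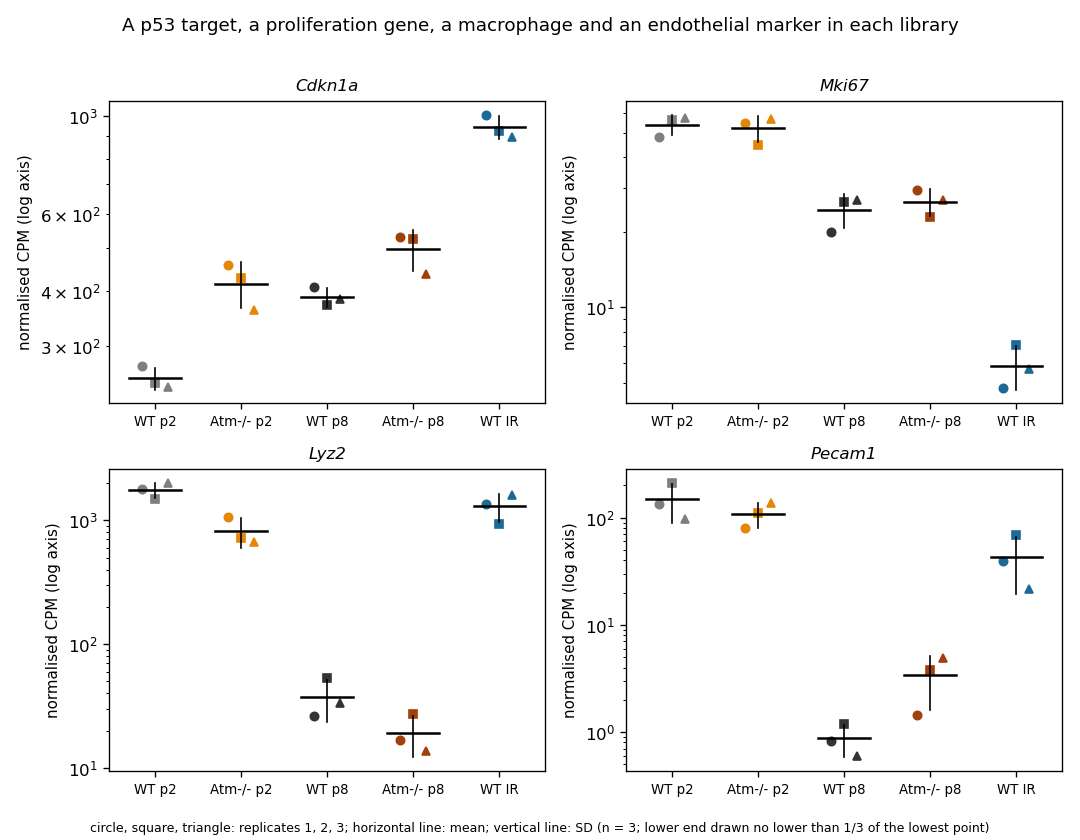
Normalised CPM (y axis, log scale) of Cdkn1a, Mki67, Lyz2 and Pecam1 in the 5 groups (x axis), with points for the 3 replicates, a horizontal line for the mean and a vertical line for the SD. Mki67 was at 54.0 CPM in Atm+/+ passage 2 and 5.83 CPM in the irradiated cells, and Lyz2 was at 1756 CPM in Atm+/+ passage 2 and 37.7 CPM in Atm+/+ passage 8.

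Irradiated Atm+/+ cells were also compared with Atm+/+ cells at passage 8. Mitosis genes were lower and some p53 target genes higher after irradiation than at passage 8, and macrophage and endothelial markers were higher. Mki67 was lower by a log2 fold change of -2.07 (SE 0.18, edgeR adjusted p = 1.8e-05) and Top2a by -2.03 (SE 0.18), and Cdkn1a was higher by 1.29 (SE 0.13, edgeR adjusted p = 5.53e-05). Lyz2 was higher by 5.11 (SE 0.37, edgeR adjusted p = 5.34e-06), and Mmp12, an elastase of macrophages, by 5.99 (SE 0.59, edgeR adjusted p = 3.87e-05). Ifi44 was higher by 1.86 (SE 0.22), while Irx1, a homeobox gene, was lower by -4.20 (SE 0.69).

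Macrophage markers had 19 of 21 higher and 2 not passing, with 20 higher over the list alone and a median of 5.42 (camera adjusted p = 4.83e-30, and 0.0230 with an estimated correlation). Endothelial markers had 14 of 16 higher and 2 not passing, with the same counts over the list alone and a median of 5.13 (camera adjusted p = 1.96e-12, and 0.126 with an estimated correlation). Mitosis genes had 21 of 35 lower and 14 not passing, with 27 lower over the list alone and a median of -1.78 (camera adjusted p = 1.71e-23, and 0.113 with an estimated correlation). DNA replication and S phase genes had 8 of 40 lower and 32 not passing, with 13 lower over the list alone (camera adjusted p = 1.94e-06, and 0.264 with an estimated correlation). Of 35 p53 target genes 8 rose and 27 did not pass, with 14 higher and 2 lower over the list alone and a median of 0.49 (camera adjusted p = 1.16e-05, and 0.113 with an estimated correlation). Interferon-stimulated genes had 18 of 56 higher and 38 not passing, with 23 higher and 2 lower over the list alone and a median of 0.71 (camera adjusted p = 1.58e-12, and 0.256 with an estimated correlation). Secretory genes of senescence had 11 of 56 higher, 3 lower and 42 not passing, with 19 higher and 6 lower over the list alone (camera adjusted p = 0.000596, and 0.282 with an estimated correlation). Cholesterol synthesis genes had 6 of 25 lower and 19 not passing, with 6 lower over the list alone (camera adjusted p = 4.23e-07, and 0.0280 with an estimated correlation).

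In total 781 genes were higher and 471 lower after irradiation than at passage 8, 1252 of 18167, of which 664 and 205 differed at least 2-fold, and 8794 genes (48.4%, against 10% by chance) did not overlap. In limma on log2(TPM + 1), where the median of all genes lay at 0.14, the split was 811 higher and 215 lower. A fit of only the 2 groups counted 6214 genes, DESeq2 1922 and the 13 libraries 4710, while leaving out 1 library gave between 722 (without Atm+/+ passage 8 replicate 2) and 2341 (without Atm-/- passage 8 replicate 3).

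The effect of irradiation in Atm+/+ cells was set against that of passage in Atm-/- cells, a difference of changes, not of levels. Matrix, contractile and interferon-stimulated genes had higher changes after irradiation, and macrophage markers fell less (median -0.62 against -6.49). Postn differed by 5.51 on the log2 scale (SE 0.51, edgeR adjusted p = 8.58e-05), Il11 by 3.44 (SE 0.37), Acta2 by 2.01 (SE 0.22) and Tagln by 2.08 (SE 0.23). Ifi44 differed by 2.91 (SE 0.31, edgeR adjusted p = 0.000167), Isg15 by 2.48 (SE 0.32), Cdkn1a by 1.64 (SE 0.19, edgeR adjusted p = 0.000228) and Tyrobp, an adaptor of myeloid receptors, by 6.82 (SE 0.51). The mitosis genes Mki67 and Birc5 differed by -2.23 (SE 0.25) and -2.50 (SE 0.31, edgeR adjusted p = 0.000437).

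Extracellular matrix and myofibroblast genes had 24 of 32 higher, 1 lower and 7 not passing, with 25 higher and 1 lower over the list alone and a median of 1.41 (camera adjusted p = 6.62e-11, and 0.146 with an estimated correlation). Senescence-associated secretory genes had 25 of 56 higher, 2 lower and 29 not passing, with 31 higher and 3 lower over the list alone and a median of 1.37 (camera adjusted p = 1.25e-06, and 0.146 with an estimated correlation). Interferon-stimulated genes had 23 of 56 higher and 33 not passing, with 30 higher over the list alone and a median of 1.22 (camera adjusted p = 6.67e-07, and 0.387 with an estimated correlation). Smooth muscle and pericyte markers had 12 of 14 higher and 2 not passing, with 12 higher and 1 lower over the list alone (camera adjusted p = 1.67e-06, and 0.120 with an estimated correlation). Macrophage markers had 16 of 21 higher and 5 not passing, with 18 higher over the list alone (camera adjusted p = 6.62e-11, and 0.120 with an estimated correlation). Mitosis genes had 14 of 35 lower and 21 not passing, with 15 lower over the list alone (camera adjusted p = 1.08e-06, and 0.387 with an estimated correlation), and their mean went from -1.015 to -0.58 without Atm-/- passage 8 replicate 1 (camera adjusted p = 0.000336). Of 35 p53 target genes 8 were higher, 2 lower and 25 did not pass, with 9 and 2 over the list alone (camera adjusted p = 0.00518, and 0.263 with an estimated correlation).

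In total 1566 genes were higher and 2353 lower, 3919 of 18167. On log2(TPM + 1) in limma, where the median of all genes lay at 0.69, 6044 genes passed with 5201 higher and 843 lower. With the strain as a block 2169 genes passed, in a fit of only the 4 groups 2518 and in the 13 libraries 6043. Leaving out 1 library gave between 1931 genes (without Atm-/- passage 2 replicate 2) and 6360 (without Atm+/+ passage 2 replicate 2).

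The fold changes of the comparisons were then set side by side over the 18167 genes. Irradiation of Atm+/+ cells and passage of Atm-/- cells, which share no library, had r = 0.188 (Spearman's rho 0.016). In this pair 266 genes rose in both, where independent lists would share 95.3, and 554 fell in both, where independent lists would share 247. Passage of Atm+/+ and of Atm-/- cells, which also share no library, had r = 0.587 (rho 0.15), with 340 genes rising in both (84.7 if independent) and 952 falling in both (202 if independent). Irradiation and passage of Atm+/+ cells share the libraries of Atm+/+ passage 2. They had r = 0.696 (rho 0.825). Simulated unchanged groups that shared simulated controls gave a mean r of 0.510 in 20 simulations and a highest of 0.524. The covariance was 1.24 against a simulated 0.132, a difference of 1.11. In this pair 1270 genes rose in both and 1470 fell in both. A pair added after seeing the data, irradiation and loss of Atm at passage 2, shares the same controls and had r = 0.811 (rho 0.816) against a simulated mean of 0.512, and a covariance of 0.719 against 0.131. In that pair 105 genes rose in both and 59 fell in both. The 3 controls cannot be split into 2 sets of at least 2, so part of the excess in the pairs that share them may come from the shared controls. Irradiation and loss of Atm at passage 8, also added after seeing the data, share no library and had r = -0.186 (rho -0.301). In the 13 libraries the 2 added pairs had 0.740 and -0.020, and leaving out 1 library gave 0.734 to 0.893 and -0.218 to -0.064. For irradiation and Atm-/- passage the correlation ran from 0.091 without 1 library to 0.354 in the 13 libraries.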

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

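The interaction contrast between genotype and passage singled out 804 genes in edgeR. The largest differences of passage effects, Atm-/- minus Atm+/+ on the log2 scale, were Plac9b (7.54), Plac9a (7.42), Cldn5 (5.23), Akap5 (4.98) and Gpihbp1 (4.68) upward. Downward they were Wfdc21 (-4.83, uncertain in size), Sytl2 (-4.58), Crh (-4.37), Cdh3 (-4.21) and Myh11 (-4.02). Among gene lists, the same contrast singled out smooth muscle and pericyte markers (median -2.06), extracellular matrix and myofibroblast genes (-1.17), senescence-associated secretory genes (-1.01), endothelial markers (2.16), epithelial markers (1.46), lysosome and autophagy genes (0.26) and DNA replication and S phase genes (0.18). With an estimated correlation 0 of these 7 lists passed in camera (adjusted p from 0.253 to 0.684), and in fry the endothelial, epithelial, lysosome and replication lists did not (0.290 to 0.401). Plac9a and Plac9b are near-identical copies and count as a single observation. Wfdc21 had 1 count in Atm-/- passage 8, and its fall with passage there was a ratio of 624 with a 95% counting interval of 112 to 24700. Of these 10 genes Plac9b, Plac9a, Cldn5, Akap5, Gpihbp1, Sytl2, Crh and Cdh3 did not pass without some single library, Cldn5, Akap5, Gpihbp1, Wfdc21, Sytl2, Crh and Cdh3 did not pass with the strain as a block, and Myh11 passed in every alternative. Akap5 fell to 3.44 without Atm+/+ passage 2 replicate 3 and to 3.37 without Atm-/- passage 8 replicate 3. Of 33 named genes passing in this contrast, 12 passed in every alternative and 20 did not pass without some single library.

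For the pair of libraries with the fewest genes detected, the tests of depth and of sex or strain were chosen after the result was seen, and the test of scatter was written before its value was known. Lower depth is argued against by the genes with a read at equal depth, which in the higher of the pair came to 85.7% of the lowest other library. Sex or strain is argued against by the same-numbered libraries at the other passage, the lower of which held 100.7% of the genes of its lower group mate. Few RNA molecules at the start would make scatter fall steeply with expression, and the shallower slope was -0.09. What sets these libraries apart stays open, and RNA damage or a contaminant may be a cause that was not tested.

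For interferon-stimulated genes, higher without Atm at either passage and after irradiation, the use of each value as a test was chosen after the result was seen, while the marker list and the fits without 1 library were planned. The libraries with the fewest genes detected are argued against by the 13-library fit, where the lowest of the 3 medians was 1.03. More macrophages are argued against by their markers, whose highest median was -0.62, and the Atm-/- strain with Xist, whose sex the labels do not give, by the list mean of 1.38 or more without replicate 3. A hypothesis left untested is that unrepaired DNA reaches cytosolic sensors, in which case cells without Atm and irradiated cells could share a trigger, and the same comparison in cells without such a sensor would decide it. A difference in culture or infection between strains stays open too.

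For matrix and smooth muscle genes, which moved apart with passage between genotypes, each value was made a test after the result was seen, while the marker lists and fits without 1 library were planned. The library with the fewest genes detected is argued against by the 13-library fit, where the list nearer to 0 had a median difference of -1.16. Macrophage and endothelial markers fell with passage in each genotype, the latter less without Atm (medians -4.33, -6.37), so neither kind is excluded. Mesothelial markers had 5 of 8 higher and 2 lower with Atm-/- passage (camera adjusted p = 0.0242, 0.290 in 13 libraries). In Atm+/+ passage 4 rose and 1 fell (0.555), and either test turned under the strict filter. In the interaction 0 of 8 passed (0.329). Resident fibroblast markers there had 2 higher, 3 lower and 18 not passing (0.162). The alternatives gave 0.00801 to 0.773, with 0.0346 without Atm-/- passage 8 replicate 2. Outgrowth by another kind of cell is not excluded. Loss of a contractile state in Atm-/- fibroblasts stays a hypothesis, which staining of single cells would decide.

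The splits were chosen after the counts were seen. For each of the 8 comparisons 1 of 10 splits of the same samples, the real one, gave as many genes as observed. The real values were the counts of the fit of all libraries, 176 to 4998. The highest other split gave 0 each time. With 10 splits a share under 0.05 cannot be reached, so they are too few for a test.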

How the results depend on the processing

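The fit of 13 libraries and the pairs of irradiation with loss of Atm were chosen after the data were seen, and the cause of each shift below was not tested. Groups of 3 libraries with 13.6 to 39.2 M counts limit what can be called, and on simulated data edgeR recovered 6% to 23% of genes changed 2-fold. Counts follow the order genotype at passage 2, genotype at passage 8, Atm+/+ passage, Atm-/- passage, irradiation, interaction, irradiation against passage 8, and irradiation minus Atm-/- passage. The fit of all libraries gave 176, 1693, 4227, 2362, 4998, 804, 1252 and 3919 genes in edgeR, and 13 libraries gave 989, 4629, 7418, 5026, 8561, 2556, 4710 and 6043. Leaving out 1 library gave 61 to 1787, 588 to 3390, 2186 to 7500, 1476 to 3544, 2677 to 8275, 79 to 4600, 722 to 2341 and 1931 to 6360. Only the groups compared gave 40, 18, 2665 and 868 for the first 4, 120 for the interaction, 6214 for irradiation against passage 8 and 2518 for the last. DESeq2 gave 863, 3525, 3589, 3472 and 1922 for the genotypes, Atm-/- passage, the interaction and irradiation against passage 8. The interaction had 518 genes with no filter, 1298 with the strict filter and 370 on log2(TPM + 0.1), and the last comparison had 6044 on log2(TPM + 1) and 6066 in the deposited subset.

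With the strain as a block the interaction had 144 genes, irradiation minus Atm-/- passage 2169, and Atm in Atm+/+ passage turned to 0.086. For the genotype comparisons, where strains share only a number, that block gave 141 and 1502.

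The correlation of irradiation with Atm-/- passage (0.188) was 0.107 with no filter, 0.354 in 13 libraries and 0.091 to 0.296 without 1 library. For passage in the genotypes (0.587) these were 0.309, 0.720 and 0.438 to 0.666, and for irradiation with Atm+/+ passage (0.696) 0.659, 0.654 and 0.655 to 0.794. Loss of Atm at passages 2 and 8 (-0.081) had -0.170 with the strict filter, -0.185 with only the groups compared and -0.155 to 0.096 without 1 library. That last sign turned in 13 libraries (0.144), without Atm+/+ passage 2 replicate 3 (0.096) and without Atm-/- passage 8 replicate 3 (0.048). Mesothelial markers turned direction in the test under the strict filter in Atm-/- passage (mean 1.15, camera adjusted p = 0.927) and Atm+/+ passage (0.08), and in the latter with only the groups compared (0.28). Epithelial markers in Atm+/+ passage turned under the strict filter (0.47). CDK inhibitors and senescence markers turned in fry after irradiation (-0.158), and interferon-stimulated genes in Atm-/- passage ran from -0.217 (turned) to 0.187 without 1 library.

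Atm, which passed in none of the 8 comparisons of all libraries, turned sign in many fits. Without 1 library its log2 fold change was -0.465 to 0.607 and -0.738 to 0.03 for the genotypes, -0.295 to 0.761 for Atm+/+ passage, -0.583 to 0.2 for Atm-/- passage, -0.241 to 0.819 for irradiation, -0.865 to 0.218 for the interaction, -0.09 to 0.194 for irradiation against passage 8 and -0.165 to 0.923 for the last comparison. In 13 libraries it turned to 0.6 between genotypes at passage 2 and 0.755 in Atm+/+ passage, and passed in irradiation minus Atm-/- passage (1.39, edgeR adjusted p = 0.0356). It was -0.002 for irradiation with DESeq2 size factors and 0.005 for the interaction with the strict filter.

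Of 84 list results with a set test in the text 67 were weaker with an estimated correlation, 15 passed with neither correlation, and 2, macrophage markers and cholesterol synthesis genes in irradiation against passage 8, passed with both. In fry 13 did not pass that camera called: extracellular matrix (0.109), NF-kB (0.317) and endothelial genes (0.395) at passage 2, endothelial (0.396) and replication genes (0.167) at passage 8, mitosis (0.250) and interferon-stimulated genes (0.159) in Atm+/+ passage, lysosome genes in Atm-/- passage (0.0729), endothelial (0.292), replication (0.401), lysosome (0.290) and epithelial genes (0.290) in the interaction, and mitosis genes in the last comparison (0.0790). Fry alone called cytosolic sensing genes at passage 2 (0.0215) and CDK inhibitors and senescence markers in Atm+/+ passage (0.0161). With no filter 6 did not pass, among them replication genes in the interaction (0.185) and mesothelial markers in Atm-/- passage (0.0731), and 4 others passed, among them cytosolic sensing genes at passage 2 (0.0146, and 0.0302 with the strict filter). The strict filter lost 5, among them endothelial markers in the interaction (0.0757), and only the groups compared lost 4, among them secretory genes (0.0660) and macrophage markers (0.0544) after irradiation and mesothelial markers in Atm-/- passage (0.221). Without 1 library 549 list results were the same, 43 weaker, 13 stronger and 1 turned. Of the results on named genes 416 were the same in 13 libraries, with 11 weaker, 17 stronger and 2 turned, and 108 were weaker with only the groups compared. Of named genes that passed in the fit of all libraries 0 turned direction.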

Other observations

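Replication-dependent histone genes were examined after the values were seen. Of 34 such genes (Hist1 to Hist4), 17 rose and 0 fell after irradiation in edgeR, with a median log2 fold change of 1.65 (camera p = 1.07e-08, unadjusted, and 0.0112 with an estimated correlation). Hist1h1c, a linker histone, rose from 108.9 ± 30.6 to 371.2 ± 18.2 CPM (SD, n = 3), by 1.77 (edgeR adjusted p = 7.48e-05). Without Atm at passage 8, 10 of the 34 rose with a median of 1.14 (camera p = 4.29e-09, unadjusted, and 0.00807 with an estimated correlation), and at passage 2 1 rose with a median of 1.00 (camera p = 8.7e-07, unadjusted, and 0.0243 with an estimated correlation). Hist1h2bc was at 62.5 ± 6.82 CPM in Atm+/+ passage 2, 93.0 ± 8.02 in Atm-/- passage 2, 74.7 ± 2.85 in Atm+/+ passage 8, 144 ± 17.4 in Atm-/- passage 8 and 132 ± 1.78 in the irradiated cells (SD, n = 3). On TPM the medians were 1.5 for irradiation, 0.36 for the genotype at passage 8 and 0.82 at passage 2. DNA replication and S phase genes had a median of -1.16 after irradiation, opposite to the histone genes.

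The tests named here were chosen after the results were seen. Histone messages with poly(A) tails may mark cells that have left the cycle, which would fit their rise beside falling replication genes, but no test here separates that from a change in how the libraries captured RNA. In the fit of 13 libraries 26 histone genes rose after irradiation with a median of 1.84, and the lowest interferon median there was 1.03. A hypothesis for another data set is that histone and interferon-stimulated messages could rise together in cells with unrepaired breaks, which sorting such cells before sequencing would decide.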
